A study of Mus musculus with 8 samples.

How the data were processed

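Total RNA of LB-22 cells was measured on Affymetrix Mouse 430_2 arrays, 1 array per sample. Per the labels' protocols, cells were transfected for 6 h with 25 pmol of Wt1 siRNA or scrambled control siRNA and RNA was extracted 48 h after transfection. Cells had been expanded with interferon gamma and were moved to a higher temperature without it at transfection. The titles and the siRNA label gave 4 control siRNA and 4 Wt1 siRNA arrays. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

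The deposited values are a linear intensity per probe set, made with MAS5 per the submitters' processing notes, and the MAS5 version is not given in the sources used here. MAS5 combines the perfect match and mismatch probes of each probe set into a signal. The table held 45101 probe sets, all above 0, and the trimmed mean (2% of probe sets left out at each end) was equal on every array, which shows a common scaling. Detection calls were not used here. Pairs of arrays shared at most 42 identical values, so none was a copy of another.

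The platform annotation was used to name probe sets and symbols were updated through Entrez gene IDs. Of 45037 probe sets that are not array controls, 34945 had 1 gene symbol (34741 updated, 204 as annotated), 932 had several and 9160 were unnamed here. Probe sets with several or no symbols were not named, and 64 control probe sets were left out. For each of 18193 named genes the probe set with the highest mean log2 signal over all 8 arrays was kept. The brighter part of these genes by mean log2 signal (9096, a share of 0.5) was tested, with a lowest mean signal of 664. Background was judged from 27 control probe sets for Bacillus subtilis transcripts, whose highest signal was 227.2 and whose 95th percentile was 109 to 179 across arrays. The number of tested genes with a group mean under that level was 0. The median SD within groups was 0.142 on the log2 scale for tested genes and 0.667 for the dimmer genes left untested, which sets the precision.

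The values were log2 transformed with no further normalization. Differences are Wt1 siRNA minus control siRNA and were tested with limma (lmFit and eBayes with an intensity trend; limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Errors given with ± after a log2 difference are the SE of the fit, and those after a signal are the SD. A fold change is 2 to the power of the log2 difference, and a percent of control is the same ratio of geometric means. On simulated data for this comparison with 9096 genes, of which 200 were changed, the procedure recovered 64% of genes changed by 0.5 and 99% of genes changed by 1 on the log2 scale, and 15 of its 178 calls were unchanged genes. The simulated noise was independent between genes, and far fewer genes were changed than the 3395 called in the data. These rates may therefore not carry over to the data.

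A set of 34 gene lists was fixed before the data were examined, of which 30 had at least 5 tested members. They cover cell type markers, genes reported as regulated by WT1, and pathways. Lists were tested against the other genes with camera, at a correlation between genes of 0.01 and at an estimated correlation. They were also tested with fry, which does not compare a list with the other genes. The genes named in the text were chosen by a rule fixed at the same time. The rule takes Wt1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, and up to 4 members of each list past the threshold with the largest absolute difference first, giving 128 genes, not all of which are discussed.

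Alternatives were the replicate number as a block, quantile normalization, median centring of arrays, an added 16 or 64 before the logarithm, no filter or a stricter filter on signal (a share of 0.25), eBayes without trend or robust, array weights, the mean over the probe sets of a gene, leaving out probe sets that can match several transcripts (suffix _s_at or _x_at), an ordinary two-sample test per gene, stricter thresholds and leaving out each array in turn. Tests chosen after seeing the data were a list of mesothelial markers, the removal of a brightness trend and a scan of gene families. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome coordinates are given, since no build is stated for the table. Probe sets unnamed here entered the probe set counts only.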

Results

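LB-22 cells, an immortalized line from embryonic mouse kidney, received an siRNA against Wt1 or a scrambled control siRNA, and total RNA was profiled on 8 Mouse 430_2 expression arrays, 4 per group. Wt1 encodes a zinc finger transcription factor of the developing kidney, the gonads and the mesothelium. The comparison asks which transcripts differ when Wt1 is lowered. Every array carried 45101 probe sets and had the same mean signal after trimming 2% of the probe sets at each end, and the number of arrays limits the precision. Across the 9096 tested genes the log2 signals correlated at 0.977 to 0.991 between arrays of the same group and at 0.940 to 0.960 between arrays of different groups. The first principal component held 61.0% of the variance and separated the groups.

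Wt1 itself was lower on all 4 arrays treated with its siRNA. The signals were 8396.8, 7129.4, 8197.2 and 7423.0 on control siRNA arrays 1 to 4 and 1679.3, 1531.0, 1316.8 and 1913.9 on Wt1 siRNA arrays 1 to 4. The group means were 7787 ± 607 and 1610 ± 251 (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give). The Wt1 siRNA group retained 20.5% of the control signal, a log2 difference of -2.28 ± 0.11 (SE; limma adjusted p = 5.91e-08). This value rests on the single Wt1 probe set, which is of the kind that can match several transcripts (suffix _s_at).

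The differences reached far beyond Wt1. The largest rises included Vnn1, which encodes the pantetheinase vanin, at 3.94-fold the control level, the calcium-activated chloride channel gene Ano1 at 3.54-fold, the stromelysin gene Mmp3 at 3.47-fold and Taldo1, encoding transaldolase of the pentose phosphate pathway, at 3.24-fold. The largest fall was that of Lrrn4, which encodes a leucine-rich repeat membrane protein, to 12.7% of control. Apmap fell to 19.6%, the kinase gene Stk26 to 21.8% and Nme1, a nucleoside diphosphate kinase gene, to 22.6%. Of 9096 genes tested with limma, 3395 (37.3%) differed at an adjusted p under 0.05, 1708 of them higher and 1687 lower after Wt1 siRNA. Among them 57 rose and 173 fell at least 2-fold, against 86 and 124 with each array centred on its median log2 signal. In 2920 of the 3395 genes every array of one group lay above every array of the other, and over all tested genes this held for 36.3%, against 2.86% by chance. The even split between higher and lower genes depended on the scaling, since the same centring gave 1584 higher and 785 lower, after a shift of the median difference over all tested genes by 0.108. Quantile normalization left the split near even, with 1778 higher and 1710 lower. The median signals of the arrays, 279.1 to 346.1, lay under the lowest tested mean signal of 664. At the level of probe sets, 2430 were higher and 2764 lower among 22518 tested, against 2459 and 1369 with median centring and 2662 and 2639 under quantile normalization.

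**Figure D1:**
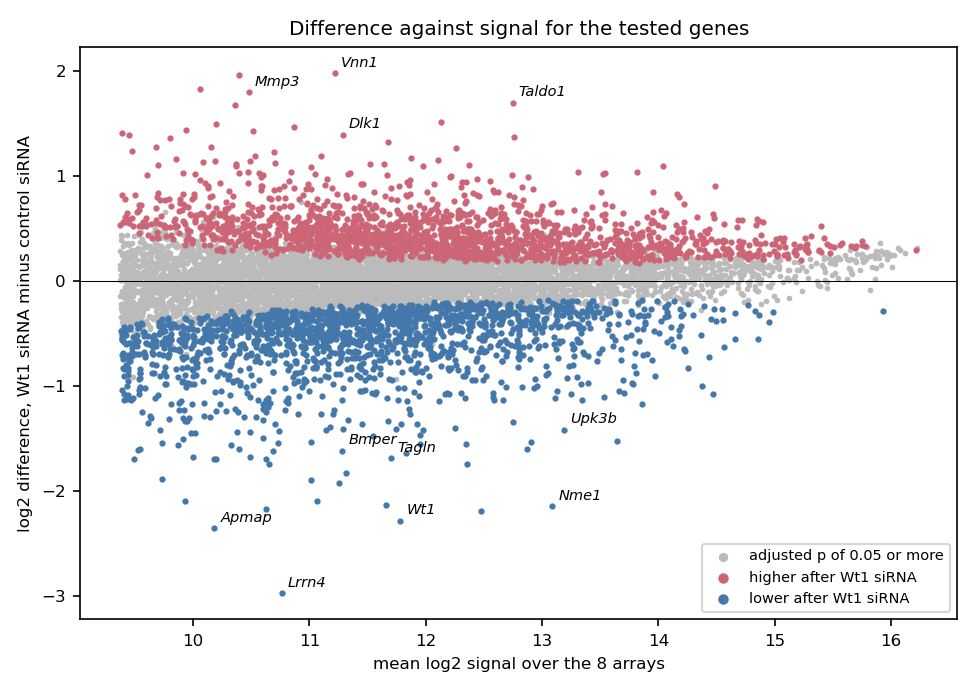
Log2 difference between the Wt1 siRNA and control siRNA groups (vertical axis) against the mean log2 signal over the 8 arrays (horizontal axis) for the 9096 tested genes, each a point. Red points are the 1708 genes higher and blue points the 1687 genes lower after Wt1 siRNA, grey points did not pass, and falls of 2-fold or more outnumber rises (173 against 57 as deposited, 124 against 86 with median centring).

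Among the 12 largest rises, the log2 difference was 1.98 ± 0.11 for Vnn1 (adjusted p = 7.19e-08), 1.96 ± 0.12 for Cgref1, 1.82 ± 0.23 for Ano1 and 1.79 ± 0.11 for Mmp3. It was 1.69 ± 0.10 for Taldo1, 1.67 ± 0.15 for Oas2, an interferon-inducible oligoadenylate synthetase gene, 1.51 ± 0.13 for Ctxn1 and 1.49 ± 0.12 for the biliverdin reductase gene Blvrb. Palm was at 1.47 ± 0.23, the clathrin adaptor gene Hip1r at 1.42 ± 0.13 and Dlk1, encoding a Notch ligand homologue, at 1.39 ± 0.17. Etv4, an ETS transcription factor gene, rose by 1.44 ± 0.34 (adjusted p = 0.00506), and with the mean over its probe sets it was at 0.60 and no longer passed (adjusted p = 0.1). Dlk1 was at 0.73 with the mean over its probe sets, and Hip1r at 0.85 when probe sets that can match several transcripts were left out.

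Among the 12 largest falls, which include Wt1, the log2 difference was -2.97 ± 0.17 for Lrrn4 (adjusted p = 7.57e-08), -2.35 ± 0.14 for Apmap, -2.20 ± 0.14 for Stk26 and -2.18 ± 0.16 for Misp3. Nme1 fell by 2.15 on the log2 scale, and its other probe set had a difference of -1.07. Sox21, an HMG box transcription factor gene, was at -2.13 ± 0.37, Clcn3, which encodes a chloride and proton exchanger, at -2.10 ± 0.14, and the cytochrome P450 gene Cyp2s1 at -1.93 ± 0.12. Trappc2, of a vesicle tethering complex, was at -1.90 ± 0.10 and Dhrs3, a retinaldehyde reductase gene, at -1.89 ± 0.38. Epcam, an epithelial adhesion gene, was at -2.10 ± 0.33 on a probe set whose control signals varied widely (2246 ± 1267, SD, n = 4), while its other probe set was at 0.19 with a mean signal of 44.4, near background.

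**Figure D2:**
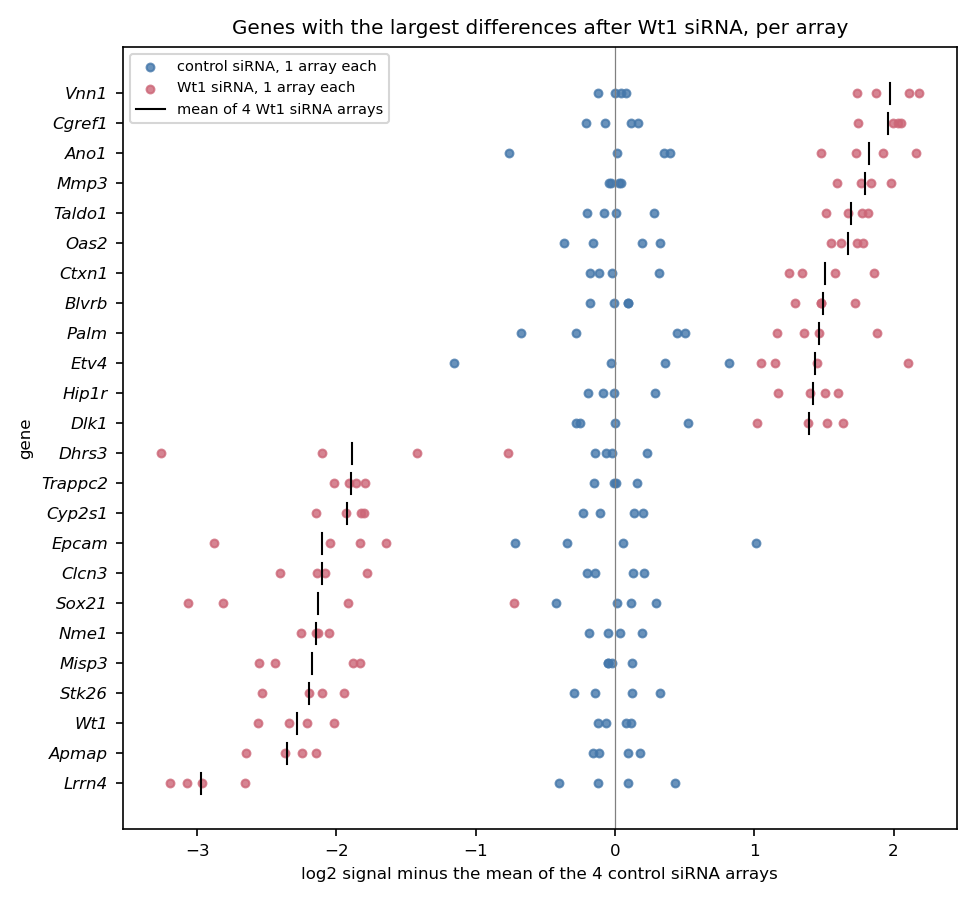
Log2 signal of each array minus the mean of the 4 control siRNA arrays (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls (rows). Blue points are control siRNA arrays, red points Wt1 siRNA arrays and black bars the mean of the 4 Wt1 siRNA arrays, and the groups do not overlap for any of these genes (Lrrn4 at -2.97, Vnn1 at 1.98).

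Podocyte genes were mostly lower after Wt1 siRNA. Of 19 tested members of the podocyte list, 10 fell, 2 rose and 7 did not pass (2 higher and 10 lower adjusted over the list alone). The actin-associated gene Synpo fell to 36.9% of control (log2 -1.44 ± 0.22), Podxl, encoding the sialomucin podocalyxin, to 40.3%, the tight junction gene Tjp1 to 51.1% and the intermediate filament gene Nes to 53.9%. The list had a median log2 difference of -0.32 and passed limma's camera test against the other genes (adjusted p = 0.0374). With the correlation between genes estimated from the arrays it did not pass camera (adjusted p = 0.381, unadjusted p = 0.0127, the lowest of all lists). The estimate for this list was -0.0075, under the preset 0.01, so correlation among its members does not account for the lost call. The call was also lost without control siRNA replicate 1 (adjusted p = 0.0566) or Wt1 siRNA replicate 3 (adjusted p = 0.0611), with the mean over probe sets (adjusted p = 0.0542) and without the intensity trend of the variance model (0.0577), and the median was -0.22 with arrays centred on their medians. The Podxl difference was -1.31 on the brighter probe set and -0.71 with the mean of both.

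Of 33 genes reported in the literature as regulated by WT1, in either direction, 12 fell, 3 rose and 18 did not pass (3 higher and 12 lower adjusted over the list alone). Bmper, encoding a secreted regulator of BMP signalling, fell to 32.6% of control, the growth arrest gene Gas1 to 34.7% and the thrombospondin gene Thbs1 to 47.3%, beside Podxl. The list was not called as shifted by camera (adjusted p = 0.249), while fry called it as lower (adjusted p = 0.00272) on the deposited scale, the only one it was run on. The list median was -0.05 as deposited, 0.01 under quantile normalization and 0.06 with median centring, so its direction depended on the scaling. Of 5 nephron progenitor genes, 2 rose and 3 did not pass (2 higher and 0 lower adjusted over the list alone). The rises were Osr1 at 0.75 ± 0.18 and the homeobox gene Hoxa10 at 0.48 ± 0.15. The Hoxa10 call was lost with the mean over probe sets (adjusted p = 0.124) and without control siRNA replicates 2 (0.0580) or 4 (0.0582) or Wt1 siRNA replicates 1 (0.0617), 2 (0.0697) or 3 (0.0592), and without Wt1 siRNA replicate 4 the list had 3 genes higher. Of 7 genes of the early nephron, 2 fell and 1 rose (1 higher and 2 lower adjusted over the list alone), namely the Notch ligand gene Jag1 at -0.84 ± 0.10, Notch2 at -0.43 ± 0.12 and Notch1 at 0.67 ± 0.11. Notch2 no longer passed when arrays were centred on their medians (adjusted p = 0.148). Of 8 ureteric bud and collecting duct genes, 2 fell (Epcam, and Gata3 at -0.64 ± 0.20), 1 rose (Etv4) and 5 did not pass (1 higher and 2 lower adjusted over the list alone). The Gata3 call was lost under quantile normalization (adjusted p = 0.0527), with no filter on signal (0.0557) and without control siRNA replicate 1 (0.0710) or Wt1 siRNA replicates 1 (0.0668) or 3 (0.0503).

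Genes of the extracellular matrix moved in both directions, with more falls than rises. Of 31 tested collagen and matrix genes, 14 fell, 6 rose and 11 did not pass (7 higher and 14 lower adjusted over the list alone). The elastic fibre gene Fbln5 fell to 34.4% of control (log2 -1.54 ± 0.08, adjusted p = 5.91e-08), the small proteoglycan gene Dcn to 38.9%, the basement membrane gene Nid2 to 40.3% and Thbs1 to 47.3%. The list median was -0.16 and the camera test passed (adjusted p = 0.0483), but not with the correlation estimated from the arrays (adjusted p = 0.570 with an estimated correlation). The call was lost without control siRNA replicate 1 (adjusted p = 0.0762) or 2 (0.0626) and without Wt1 siRNA replicate 2 (0.0891) or 3 (0.0662). It was also lost with the replicate number as a block (adjusted p = 0.0577), among the brightest share of 0.25 of the genes (0.0790, median -0.08), without the intensity trend (0.0607) and without probe sets that can match several transcripts (0.0551). The median was -0.05 with arrays centred on their medians and -0.26 under quantile normalization.

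Of 13 kidney stroma genes, 5 were lower, 3 higher and 5 did not pass (3 higher and 5 lower adjusted over the list alone). Their median was 0.04, and with median centring 4 were higher and 4 lower. The matrix gene Mgp fell to 36.6% of control and Dcn to 38.9%, while Dlk1 rose 2.62-fold and Gdf10, encoding a TGF-beta family ligand, 1.94-fold. Of 23 mesenchymal genes, 8 fell, 5 rose and 10 did not pass (6 higher and 8 lower adjusted over the list alone). With median centring 7 of them rose and 4 fell. The smooth muscle actin-binding gene Tagln fell to 30.9% of control and the cadherin gene Cdh11 to 54.6%. Epithelial junction and keratin genes were lower in 6 of 13 cases and higher in 2 (3 higher and 6 lower adjusted over the list alone), including Epcam, the polarity gene Crb3 at -0.95 ± 0.17, the junctional adhesion gene F11r at -0.58 ± 0.09 and the keratin gene Krt8 at 0.55 ± 0.15. Another probe set of Crb3, with a mean signal of 543, showed a difference of 0.0033. None of these lists was called as shifted by camera, while fry called the epithelial list as lower (adjusted p = 0.00272).

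Markers of other cell types were few among the tested genes. Of 4 endothelial markers, 2 fell (Cd34 at -0.47 ± 0.12 and Kdr at -0.45 ± 0.11) and 1 rose (Eng at 0.53 ± 0.17), with 1 higher and 2 lower adjusted over the list alone. The Cd34 and Kdr calls were lost with arrays centred on their medians (adjusted p = 0.106 and 0.0894), and the Eng call with the mean over probe sets (adjusted p = 0.548), with no filter on signal (0.0577) and without control siRNA replicate 2 (0.0789) or Wt1 siRNA replicates 2 (0.0584) or 4 (0.0698). Of 3 leukocyte markers, Cd68 rose 1.98-fold and the receptor gene Csf1r fell to 59.2% of control (1 higher and 1 lower adjusted over the list alone), though Csf1r did not pass with the mean over its probe sets (adjusted p = 0.198). Of 3 neuronal and glial markers, Ncam1 fell to 67.8% of control (0 higher and 1 lower adjusted over the list alone). The 2 tested muscle markers did not pass (0 higher and 0 lower adjusted over the list alone).

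**Figure D3:**
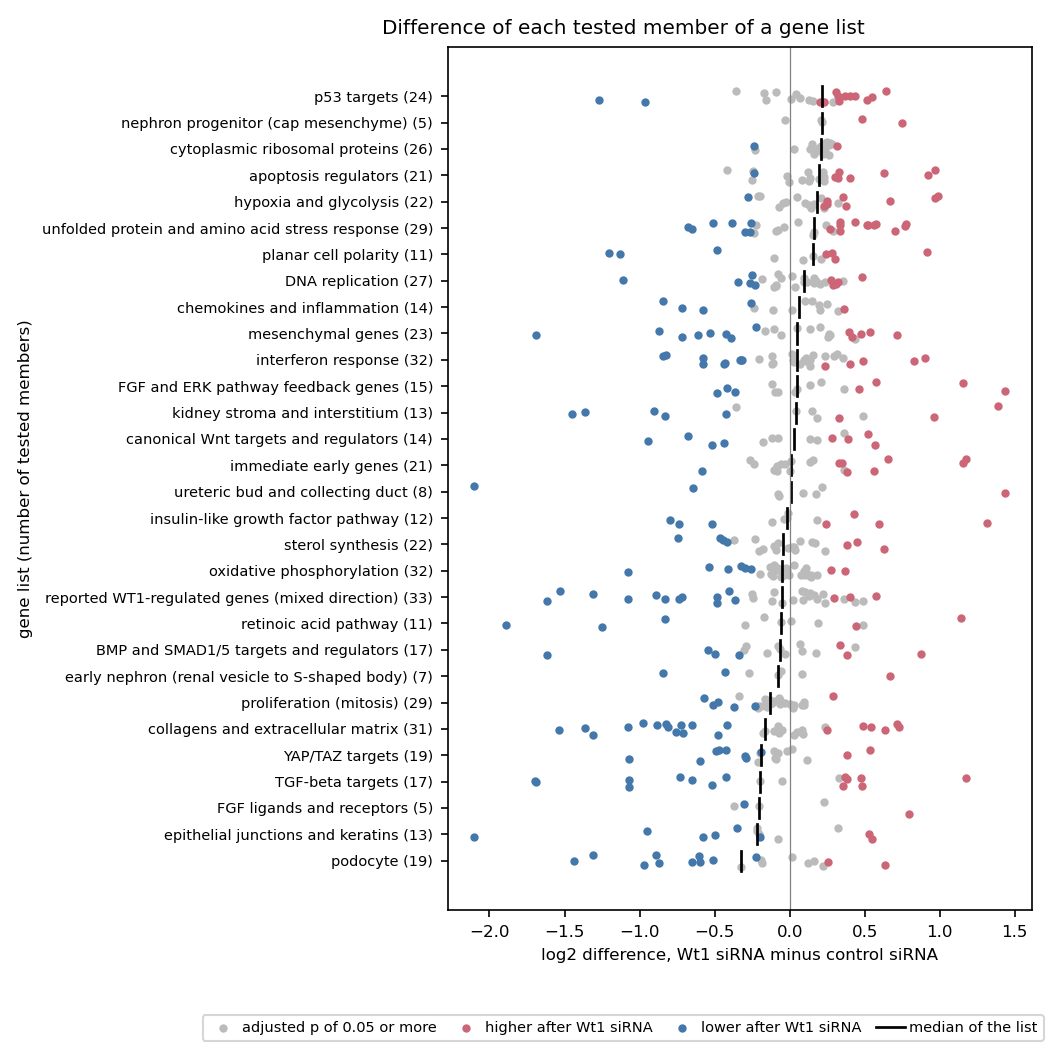
Log2 difference between the Wt1 siRNA and control siRNA groups (horizontal axis) for each tested member of the 30 gene lists with at least 5 tested members (rows, number of tested members in brackets). Points are genes, red higher, blue lower and grey not passing, and the black bar is the list median, which ranged from -0.32 for podocyte genes to 0.22 for p53 targets.

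Several genes of TGF-beta and mechanical signalling were lower. Of 17 TGF-beta targets, 8 fell, 6 rose and 3 did not pass (7 higher and 8 lower adjusted over the list alone). With median centring 7 of them rose and 7 fell. The ligand gene Tgfb3 fell to 30.8% of control, Tagln to 30.9% and Bhlhe40, a transcriptional repressor gene, to 47.7%, while the AP-1 gene Junb rose 2.25-fold. Of 19 YAP/TAZ targets, 8 fell, 2 rose and 9 did not pass (2 higher and 8 lower adjusted over the list alone), with Ccn2, encoding connective tissue growth factor, at 47.7% of control and Dock5 at 66.0%. With arrays centred on their medians, 2 YAP/TAZ targets fell and 2 rose. Neither list was called (camera adjusted p = 0.271 and 0.0828), while camera called the YAP/TAZ list as lower with no filter on signal (adjusted p = 0.0297) and without control siRNA replicate 3 (0.0468), against adjusted p = 0.473 with an estimated correlation.

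Of 17 BMP pathway genes, 4 fell, 3 rose and 10 did not pass (3 higher and 4 lower adjusted over the list alone), with Bmper at -1.62 ± 0.12 and the activin antagonist gene Fst at 0.88 ± 0.10. Of 14 genes of canonical Wnt signalling, 4 rose, 4 fell and 6 did not pass (4 higher and 4 lower adjusted over the list alone), with the receptor gene Fzd7 at -0.94 ± 0.10 and Ccn4 at -0.68 ± 0.08. Of 11 planar cell polarity genes, 4 rose, 3 fell and 4 did not pass (4 higher and 3 lower adjusted over the list alone). The receptor genes Ror1 and Fzd6 were at -1.20 ± 0.11 and -1.13 ± 0.11 and the adaptor gene Dvl2 at 0.91 ± 0.10. With the mean over probe sets Fzd7 was at -1.63, Ror1 at -0.75 and Fzd6 at -0.55, where Fzd6 no longer passed (adjusted p = 0.0596). With median centring 2 planar cell polarity genes rose and 2 fell.

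Of 15 FGF and ERK feedback genes, 4 rose, 3 fell and 8 did not pass (4 higher and 3 lower adjusted over the list alone), the rises including Etv4 and the AP-1 gene Fosl1 at 1.15 ± 0.16. With median centring 5 of them rose and 0 fell, by limma. Of 5 tested FGF ligands and receptors, the carrier protein gene Fgfbp3 rose by 0.80 ± 0.13 and Fgfr2 was at -0.30 ± 0.10 with an adjusted p of 0.0369, while 3 did not pass (2 higher and 1 lower adjusted over the list alone). Fgfr2 had the opposite sign, 0.13, when probe sets that can match several transcripts were left out, and its call was lost whichever array was left out except Wt1 siRNA replicate 4, with adjusted p up to 0.0968. The Fgfr2 call was also lost with the replicate block (adjusted p = 0.0620), quantile normalization (0.0750), median centring (0.383), no filter on signal (0.0574) and the mean over probe sets (0.206). Of 11 retinoic acid pathway genes, 3 fell, 2 rose and 6 did not pass (2 higher and 4 lower adjusted over the list alone). Dhrs3 fell to 27.0% of control, the transglutaminase gene Tgm2 to 42.0% and the retinoic acid synthesis gene Aldh1a2 to 56.3%, while Cyp26b1, encoding an enzyme that degrades retinoic acid, rose 2.20-fold. Tgm2 did not pass without its shared-sequence probe sets (adjusted p = 0.0516). Of 12 insulin-like growth factor pathway genes, 4 rose, 3 fell and 5 did not pass (4 higher and 3 lower adjusted over the list alone), with the binding protein genes Igfbp3 at 1.32 ± 0.19, Igfbp5 at -0.80 ± 0.20 and Igfbp6 at -0.74 ± 0.12.

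Genes of stress and cell death pathways were more often higher than lower. Of 24 p53 targets, 11 rose, 2 fell and 11 did not pass (11 higher and 3 lower adjusted over the list alone). The rises were moderate, such as Ei24 at 0.64 ± 0.07 and the nuclease gene Aen at 0.55 ± 0.09 (0.36 with the mean over probe sets), whereas the largest differences were falls of Eda2r (-1.27 ± 0.10) and Sesn1 (-0.96 ± 0.12). Of 21 apoptosis regulators, 7 rose, 1 fell and 13 did not pass (7 higher and 1 lower adjusted over the list alone). Bid, which promotes death at the mitochondrion, rose 1.95-fold and Cflar, which inhibits caspase activation, 1.89-fold. Other Cflar probe sets went both ways and the mean over them did not pass (adjusted p = 0.311). Of 21 immediate early genes, 7 rose, 1 fell and 13 did not pass (7 higher and 1 lower adjusted over the list alone), led by Junb at 1.17 ± 0.12 and Fosl1 at 1.15 ± 0.16. The camera adjusted p was 0.129 for p53 targets, 0.0828 for apoptosis regulators and 0.257 for immediate early genes, so none of these lists was called. With no filter on signal camera called the p53 list (adjusted p = 0.0297) and the apoptosis list (0.0297) as higher, the latter also without control siRNA replicate 3 (0.0468), against adjusted p = 0.473 and 0.580 with an estimated correlation.

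Of 29 genes of the unfolded protein and amino acid stress response, 12 rose, 7 fell and 10 did not pass (12 higher and 7 lower adjusted over the list alone). Dnajb9, a chaperone cofactor gene of the endoplasmic reticulum, rose 1.71-fold, Slc7a5, a neutral amino acid transporter gene, 1.62-fold and the transcription factor gene Ddit3 1.72-fold, while the disulfide isomerase gene Pdia6 was at -0.68 ± 0.10. Ddit3 did not pass with the mean over its probe sets (adjusted p = 0.212), and Pdia6 was then at -0.34. Of 22 hypoxia and glycolysis genes, 8 rose, 1 fell and 13 did not pass (8 higher and 1 lower adjusted over the list alone), with the phosphofructokinase gene Pfkl at 0.99 ± 0.11 (0.63 with the mean over probe sets), the mitophagy gene Bnip3 at 0.97 ± 0.14 and the oxidoreductase gene Ero1a at 0.67 ± 0.07. Of the hypoxia and glycolysis genes, 5 rose and 2 fell under quantile normalization, and 5 rose with median centring. Of 32 oxidative phosphorylation genes, 6 fell, 2 rose and 24 did not pass (2 higher and 6 lower adjusted over the list alone). Cox5a, a subunit gene of cytochrome c oxidase, fell to 47.3% of control on its brightest probe set and was also lower on its 2 other probe sets, and the complex I subunit gene Ndufb3 fell to 69.1%. Of 22 sterol synthesis genes, 4 fell, 3 rose and 15 did not pass (3 higher and 4 lower adjusted over the list alone), with Insig1, a feedback regulator gene, at -0.75 ± 0.16 and Hsd17b7 at 0.63 ± 0.12, which did not pass with the mean over its probe sets (adjusted p = 0.0955). None of these lists was called (camera adjusted p = 0.367, 0.0756, 0.506 and 0.825, in this order). Camera called the oxidative phosphorylation list as lower under quantile normalization (adjusted p = 0.0240), and the hypoxia list as higher with the mean over probe sets (0.0186) and with no filter on signal (0.0297), against adjusted p = 0.902 and 0.473 with an estimated correlation.

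Most proliferation genes did not pass. Of 29 mitosis genes, 5 fell, 1 rose and 23 did not pass (1 higher and 5 lower adjusted over the list alone). The cyclin gene Ccnb2 fell to 67.3% of control and the spindle motor gene Kif11 to 70.2%. With median centring 2 of the mitosis genes fell and 1 rose, and under quantile normalization 7 fell and 1 rose. The list was not called (camera adjusted p = 0.119, and adjusted p = 0.901 with an estimated correlation), but camera called it as lower under quantile normalization (adjusted p = 0.0240) and with the mean over probe sets (0.0182). Of 27 DNA replication genes, 5 rose, 5 fell and 17 did not pass (5 higher and 5 lower adjusted over the list alone), and Mcm4, a helicase subunit gene, fell to 46.4% of control (log2 -1.11 ± 0.07, adjusted p = 1.28e-07) while the flap endonuclease gene Fen1 was at 0.48 ± 0.13. With median centring 6 of them rose and 1 fell.

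Interferon response genes moved in both directions, with 9 of 32 lower, 5 higher and 18 not passing (7 higher and 10 lower adjusted over the list alone). Oasl1 rose 1.87-fold and Stat2 1.78-fold, while the chemokine gene Cxcl10 fell to 55.8% of control and Irf9, which binds DNA with STAT proteins, to 56.4%. With median centring 7 of them rose and 4 fell, and under quantile normalization 5 rose and 14 fell. The cells of both groups had been expanded with interferon gamma, which was withdrawn at transfection, per the labels. Of 14 chemokine and inflammation genes, 4 fell, 1 rose and 9 did not pass (1 higher and 4 lower adjusted over the list alone), with the colony stimulating factor gene Csf1 at -0.72 ± 0.09 and the ubiquitin-editing gene Tnfaip3 at -0.58 ± 0.09.

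Most cytoplasmic ribosomal protein genes did not pass. The median log2 difference of 26 tested members was 0.21, with the opposite sign, -0.01, under quantile normalization and 0.32 with median centring, and Rplp2 rose by 0.31 ± 0.09, Rpl11 was at -0.24 ± 0.09 and 24 did not pass (0 higher and 0 lower adjusted over the list alone). Without Wt1 siRNA replicate 4, 4 of them were higher and 0 lower by limma. The list passed camera (adjusted p = 0.0483), but not with the correlation estimated from the arrays (adjusted p = 0.901 with an estimated correlation) nor with fry (adjusted p = 0.113). Its call was lost without control siRNA replicates 1 (adjusted p = 0.116) or 4 (0.0779) and without Wt1 siRNA replicates 3 (0.0662) or 4 (0.0824). It was also lost with the replicate block (adjusted p = 0.0577), in the brightest share (0.112), without the intensity trend (0.0607), with array weights (0.0602), with the mean over probe sets (0.0542) and without probe sets that can match several transcripts (0.0855). The phage cre spike-in control, which holds no RNA of the cells, was 0.23 apart on the log2 scale in the same direction without passing (58103 ± 13309 against 48871 ± 5282, SD, n = 4; exact two-sided permutation p = 0.257), and 0.081 apart without Wt1 siRNA replicate 4. Rplp2 did not pass under quantile normalization (adjusted p = 0.0976), and Rpl11 was lost whichever array was left out except control siRNA replicate 1, with adjusted p up to 0.153. The Rpl11 call was also lost with the replicate block (adjusted p = 0.0685), median centring (0.536, difference -0.13), no filter on signal (0.0946), no intensity trend (0.0710) and the mean over probe sets (0.0594).

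In all, camera called 3 of the 30 lists with at least 5 tested members, the podocyte and matrix lists as lower and the ribosomal list as higher. With the correlation between genes estimated from the arrays it called 0 lists. The 2 lists with an unadjusted camera p under 0.05 were podocyte (0.0127) and hypoxia (0.0424). Their estimated correlations, -0.0075 and 0.0102, were under or near the preset 0.01. The rotation test fry asks whether the members of a list move one way on balance, without comparing them with the other genes. With 37.3% of all tested genes past the threshold, a fry call does not set a list apart from them. Asked for changes in either direction, fry called 28 of the 30 lists. For a shift one way, run on the deposited scale only, fry called 12 lists. As lower it called the podocyte (adjusted p = 0.000229), matrix (0.00272), reported WT1-regulated (0.00272), epithelial (0.00272), TGF-beta (0.00272) and YAP/TAZ (0.00435) lists. As higher it called the hypoxia (0.00137), p53 (0.00488), immediate early (0.00711), apoptosis (0.0101), unfolded protein (0.0263) and nephron progenitor (0.0398) lists. The immediate early median was 0.011 as deposited and -0.0009 under quantile normalization. Over all 9096 tested genes 1708 were higher and 1687 lower, and counts of members near that share do not set a list apart. The median, the mean and the camera direction did not share a sign for the lists of kidney stroma, ureteric bud, interferon response, mesenchymal genes, canonical Wnt, planar cell polarity, chemokines, FGF ligands and insulin-like growth factor genes. With arrays centred on their medians fewer genes were lower in several lists, namely 2 of the unfolded protein response, 3 of the epithelial, 4 of the mesenchymal, 2 of the oxidative phosphorylation, 2 of the canonical Wnt, 1 of the sterol and 1 of the BMP genes, and 8 of the reported WT1-regulated genes were then lower and 6 higher. Without Wt1 siRNA replicate 4, 6 FGF and ERK feedback genes were higher and 2 lower, 3 chemokine genes higher and 3 lower, 2 FGF ligands and receptors higher, 3 YAP/TAZ targets higher, 3 epithelial genes higher, 1 podocyte gene higher and 0 endothelial markers higher by limma.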

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

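The tests of the brightness trend, the spike-in probe sets, the slope of Wt1 siRNA replicate 4 and the other probe sets of strong falls, and the criterion for the ribosomal median without that array, were chosen only after the results were seen. In 23 of 268 groups of 4 values, a single array lay so far from the other 3 that its gap to the nearest, as a share of the range, passed the limit of Dixon's test, against 13.4 such groups by chance at 1 in 20. Of these, 9 fell on control siRNA replicate 3 and 9 on Wt1 siRNA replicate 4, with 2 on control siRNA replicate 2, 2 on Wt1 siRNA replicate 3 and 1 on control siRNA replicate 1.

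On Wt1 siRNA replicate 4 the actin 3' control was at 107397.5 (others up to 75044.6), the bioB spike at 1303.8, the bioD spike at 24211.3 (others up to 15963.5), the cre spike at 78034.5 (others up to 52501.8) and Rplp2 at 70128.6 (others up to 55848.6). On the same array Igfbp3 was at 6741.7, above the other Wt1 siRNA arrays, and Fosl1 at 4740.3, Hoxa10 at 2250.8 and Insig1 at 1310.6 were below them. On control siRNA replicate 3 the median signal was 279.1, below the 336.1 to 346.1 of the other controls, Gdf10 was high at 3353.4, Uhrf1 at 9947.8, Cd34 at 2999.1, Fzd6 at 6552.1 and Bmper at 4655.9, and Stat2 was low at 2953.5, Axl at 17252.3 and Spry1 at 1600.3. Single arrays also stood apart for Junb (4392.5, low on Wt1 siRNA replicate 3), Hsd17b7 (2118.4, high on Wt1 siRNA replicate 3), Krt8 (1152.3, low on control siRNA replicate 2), Csf1r (1718.6, high on control siRNA replicate 2) and Tjp1 (8652.8, low on control siRNA replicate 1).

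Wt1 siRNA replicate 4 stood apart from its group at the bright end. A weaker response to the siRNA in that sample was tested by regressing its deviation from another Wt1 siRNA array on the difference between the remaining 2 and the controls. The mean slope over the 3 choices was -0.035 (SD 0.045), but the bound for it was settled after slopes had been seen, and Wt1 itself had its highest signal of the group there (1913.9, against 1316.8 to 1679.3), so a weaker response stays open. A difference in scaling of the bright end is consistent with the spike-in controls, which hold no RNA of the cells, since 18 of 18 spike-in probe sets were brighter there than on each of the other 3 Wt1 siRNA arrays, although the amount of spike added is not separated from scaling by this. The spike-in probe sets report only a few transcripts, among them bioB, bioD and cre, so they are not 18 separate observations. The gene counts without Wt1 siRNA replicate 4 were 1803 higher and 1653 lower.

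The ribosomal protein genes, with a median log2 difference of 0.21, are among the brightest on the array. In the brightest of 10 equal bins of tested genes, which holds 23 of the 26 ribosomal genes, the median difference was 0.13, and in the dimmest it was -0.10. After the trend with brightness was subtracted, the ribosomal median lay at the 85.8 percentile of 10000 random lists matched on brightness, consistent with a difference between arrays that grows with brightness and may not concern ribosomal genes in particular. Without Wt1 siRNA replicate 4 the median was still 0.14, with 4 members higher and 0 lower by limma, which argues against that array as the only source. The median was similarly small, 0.15, without control siRNA replicate 1. A partial contribution of Wt1 siRNA replicate 4 stays open. The 0.14 is a share above 0.5 of the full value by less than the SD of 0.043 over medians with 1 array left out. A response of the genes to Wt1 siRNA also stays open.

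Strong falls outnumbered strong rises, 173 against 57 at 2-fold or more, and 84 of the 100 genes with the smallest p were lower. The size of this excess depended on the scaling, with 165 against 55 under quantile normalization and 124 against 86 with median centring, so scaling may account for part of it. Probe sets that do not report their gene are argued against by the other tested probe sets of the genes with strong falls. Of those, 128 of 131 (97.7%, 95% exact interval 93.5 to 99.5%) also fell. For strong rises, 35 of 38 other probe sets (92.1%) also rose. Probe sets of the same gene are not independent, so the interval is too narrow. Silencing of transcripts other than Wt1 by the siRNA could contribute to the 173 falls and cannot be told apart from an effect of Wt1, because a single siRNA label is given and its sequence was not used here.

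For the counts of the comparison, all 35 splits of the 8 arrays into 4 and 4 were run. Only the real split, 1 of 35, gave as many as 3395 genes or 5194 probe sets, and the highest count of the other splits was 0 for both. Every other split mixes control siRNA and Wt1 siRNA arrays on both sides. The difference between the groups then adds to the spread within each side and lowers the count. The splits therefore give no more than 1 of 35 against a random grouping of the arrays. Chance differences between cultures or transfections are not excluded for these counts, since the labels do not state separate cultures. For the gene lists, 11 of the 35 splits called at least 3 lists and the highest of the others called 7, so chance is not excluded for the number of lists called.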

How the results depend on the processing

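Only the removal of the brightness trend was chosen after the results were seen. The Wt1 fall was called under every alternative that gave it a value, with leave-one-out values from -2.37 to -2.19. The alternative without _s_at and _x_at probe sets left out the only Wt1 probe set, which has the suffix _s_at, and could not test the fall. Counts of genes were within 1.5 times the 3395 under all alternatives except stricter ones, which gave 1003 at 1.5-fold or more, 2185 at an adjusted p under 0.01 and 1870 in the brightest share of 0.25, where fewer genes were tested. Leaving out 1 array gave 2810 to 3456 genes. Probe sets numbered 2209 at 1.5-fold or more and 2720 at an adjusted p under 0.01, and 3774 to 5763 with 1 array left out. List calls were less stable than gene calls. Camera called 3 lists, and the count was 0 with an estimated correlation, 12 with fry, 7 with no filter on signal, 1 in the brightest share, 0 without the intensity trend and 1 without _s_at and _x_at probe sets. The mean over probe sets called 3 lists, of which 1 was shared, and quantile normalization 4, of which 2 were shared and all lower. With 1 array left out the count ranged from 0 (without control siRNA replicate 1 or Wt1 siRNA replicate 3) to 5 (without control siRNA replicate 3). The ribosomal list reversed under quantile normalization (-0.011), which forces equal bright ends, and Fgfr2 reversed without _s_at and _x_at probe sets (0.13), where another probe set stands for the gene. For the other changes the cause was not tested. Lists not called had no direction to lose.

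Of 128 named genes, 91 were called under every alternative that gave them a value, and so were 23 of the 24 with the largest differences. A gene that a setting left out, such as a dimmer gene in the brightest share, was not counted as lost there. The two-sample test and the stricter thresholds were read only as counts, not for each named gene. For the 127 other than Wt1, 2352 results kept direction and call, 111 kept direction and lost the call and 1 reversed, and 12 genes lost the call when some array was left out. Same-numbered arrays showed little shared deviation (correlations 0.084, -0.077, 0.083 and 0.039), and 4 of the 8 arrays correlated best with their own number. The samples were treated as unpaired, though these values cannot show that they were not prepared in pairs. With the replicate block the fit called 3414 genes, 4608 probe sets and 1 list, the podocyte list. Dimmer genes were tested only in the fit with no filter on signal, which called 3258 genes, 2908 of them shared.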

Other observations

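The tests on mesothelial markers and on intraflagellar transport genes were both chosen only after values of some of their genes had been seen. Wt1 is a known marker of the mesothelium, and a list of 18 mesothelial genes was written after the values of some of them had been seen. Of 14 tested members, 11 were lower after Wt1 siRNA, 1 was higher and 2 did not pass. Besides Lrrn4 (-2.97 ± 0.17), the uroplakin gene Upk3b fell from a mean signal of 15246 to 5715 (log2 -1.42 ± 0.08), Gpm6a was at -1.13 ± 0.09, the zinc finger gene Bnc1 at -0.91 ± 0.11 and the mesothelin gene Msln at -0.75 ± 0.09, while Krt8 was higher at 0.55 ± 0.15. The list median was -0.81 on the deposited scale, -0.81 under quantile normalization and -0.70 with median centring, and it ranged from -0.89 to -0.78 with 1 array left out. Camera gave p = 5.46e-07, and p = 0.034 with an estimated correlation (0.0226 to 0.0498 with 1 array left out).

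A hypothesis is that a mesothelium-like program may depend on Wt1 in these cells. Because the list was written with values in view, a further test, also settled after values had been seen, used the 8 members outside the named genes and the 100 genes of smallest p. Their median was -0.52, below all but 0.01% of 10000 random lists matched on brightness, with 6 lower and 0 higher by limma, but camera with an estimated correlation gave p = 0.121, so the hypothesis stays open. Of the 14 members, 6 also stand on the lists fixed in advance, and whether these cells are of mesothelial origin was not tested.

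A scan of 146 gene families by shared symbol stem put the intraflagellar transport genes, which build cilia, first. Of 14 tested Ift genes, 7 were lower and 0 higher by limma (median -0.36, -0.29 under quantile normalization and -0.25 with median centring), with Ift46 at -0.70 ± 0.10 and Ift74 at -0.64 ± 0.09. The family did not pass camera over the 146 families (adjusted p = 0.0734). With an estimated correlation the camera adjusted p was 0.995 for every family scanned (unadjusted p = 0.0863 for Ift). That setting separated none of the families, so a joint fall of the Ift genes was not supported but is not excluded by it.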
